A study of Mus musculus with 6 samples.

How the data were processed

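The data are RNA-seq gene counts from F4/80+ CD11b+ peritoneal macrophages of wild-type and Zeb1 (+/-) mice, with 3 libraries per genotype and 2 mice pooled for each library. Per the labels, RNA was extracted with RNAzol and libraries were made with a stranded TruSeq mRNA kit. The deposited table holds estimated counts per gene in 1 column per library, made by the authors with STAR, RSEM and edgeR per the submitters' processing notes, which give no versions or roles, on the mouse build GRCm38. All values were whole numbers with unequal column totals, so the expected counts of RSEM appear to have been rounded before they were deposited. The strand setting of the counting and the annotation release were not given in the sources used here.

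Gene symbols and identifiers were taken from the table, and coordinates from a GENCODE annotation of GRCm38, in which 84.9% of the gene identifiers matched with their version and 99.3% without it. Where a symbol stood for several identifiers, the one with the most counts kept it, and 122 others were named by identifier. Each column was mapped to its sample by the identifier in the sample's description, and 0 columns were left unmapped. Wild-type and Zeb1 (+/-) samples are numbered by the replicate number in their titles; nothing in the labels pairs the numbers across genotypes, so the number is not in the model.

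The model was fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 12940 genes. Library sizes were scaled by TMM factors, which lay between 0.976 and 1.01, and genotype was tested by the quasi-likelihood method without robust moderation. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic, and 95% confidence intervals used the t distribution with the total degrees of freedom of the fit. CPM values use the TMM-scaled library sizes, except the sums of structural RNA and haemoglobin, which use the raw totals. Means are given with the SD over 3 libraries. With totals of 17859872 to 42165006 counts, 1 CPM stands for 17.9 to 42.2 counts in a library. Intervals cover the spread between pooled libraries, not between single mice.

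Before the data were examined, 33 gene lists were fixed, along with the rule for which genes to name. They cover large and small peritoneal macrophages, MHC class II presentation, core macrophage genes, classical and alternative activation, chemokines, and chemokine and cytokine receptors. They also cover responses to type I interferon and interferon gamma, matrix and proteases, complement and coagulation, phagocytosis and scavenger receptors, and cholesterol and lipids. Further lists cover glycolysis and hypoxia, oxidative phosphorylation, lysosome and autophagy, cell cycle, unfolded protein response, epithelial genes reported to be repressed by ZEB1, and mesenchymal genes. The rest serve as checks of RNA and sort: immediate-early, heat shock, mitochondrial and sex-linked genes. With them are markers of B cells, T and NK cells, neutrophils, eosinophils and mast cells, dendritic cells, monocytes, mesothelium and fibroblasts, and erythroid cells and platelets. The 31 lists with 3 or more tested genes were tested by camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over those 31. A correlation estimated per list and the fry test were alternatives. Camera compares a list with all other genes, while fry asks whether its genes move on balance one way. Members were also adjusted over the list alone. The genes named are Zeb1 and the 12 highest and 12 lowest log2 fold changes among changed genes with a symbol, with groups that did not overlap and a mean of at least 2 CPM in either genotype. From each list come the members past the threshold (all if at most 6, else 4), or failing any the member with the smallest p. Ccr2, Mmp9, Cd74, Itgam and Adgre1 are named as well, because of the sort and of what was already known of the study. They were therefore not chosen without prior knowledge of it. Other genes are named as examples of their list, or in the closing section where that is said.

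Alternatives fixed in advance were RLE size factors, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, the Wald test of DESeq2 1.42.0, limma-voom and robust moderation. With them were an adjusted p under 0.1, a change of at least 2-fold, and each library left out in turn. A pair was added after the data were seen: the split of the libraries by structural RNA as a term, and the mean log2 CPM of the B cell list without Bank1 as a covariate. Uniqueness of named genes was read as the share of their 50-base stretches that occur in annotated transcripts of other genes.

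The model was tested on 20 sets of simulated counts with the mean of each gene and the dispersion trend of these libraries. Spread of single genes around that trend was not simulated, nor were differences between libraries other than their scaled totals. Of 200 genes planted as changed, it found 66.9% of those changed 1.5-fold, 86.7% at 2-fold and 95.1% at 3-fold, and 4.17% of its calls were unchanged genes. A list of 20 genes planted at a log2 fold change of −0.5 was called in 20 of the 20 sets, with 0.1 other lists called per set. Simulated genes varied independently of each other, whereas the correlation estimated within the real lists reached 0.87 (B cell). The sets therefore do not show how often camera calls lists whose members vary together. Library pairs were checked for duplicates: over genes with counts, chi-square per degree of freedom was 13.4 to 42.2, above the value near 1 that a library sequenced again would give. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Single-mouse values and the raw reads were not used here.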

Results

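Messenger RNA was sequenced from macrophages that had been washed from the peritoneal cavity of untreated C57BL/6 mice and sorted by flow cytometry as F4/80+ CD11b+ cells. There were 3 wild-type libraries and 3 Zeb1 (+/-) libraries, each from a pool of 2 mice aged 6 to 8 weeks. The gene table held 48709 genes, of which 27608 had no count in any library. Total counts per library were 33358835, 28073386 and 18574049 in wild-type replicates 1, 2 and 3, and 17859872, 42165006 and 33650529 in Zeb1 (+/-) replicates 1, 2 and 3. The Y-linked gene Ddx3y had 0 counts in all 6 libraries. Xist, the RNA of X inactivation, was at a mean of 653 and 615 CPM (counts scaled to library size) in wild-type and Zeb1 (+/-) libraries. The libraries also differed within the wild-type group. Small structural RNAs (small nuclear, ribosomal, ribozyme and miscellaneous classes) summed to 4.14 and 8.69 CPM in wild-type replicates 1 and 2 and to 42.2 CPM in wild-type replicate 3. In the Zeb1 (+/-) libraries they summed to 43.6, 45.5 and 44.3 CPM. The low class held wild-type libraries only. Values from a fit with this split as a term, in which wild-type replicate 3 alone stood against the Zeb1 (+/-) libraries, are given below for part of the results.

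Zeb1 (ENSMUSG00000024238.13), which encodes a zinc-finger transcription factor that binds E-box sequences, lies on chromosome 18 from 5591860 to 5775467 on the plus strand of GRCm38. Its expression was 5.44, 7.56 and 7.22 CPM in wild-type replicates 1, 2 and 3, and 3.85, 3.45 and 3.62 CPM in Zeb1 (+/-) replicates 1, 2 and 3. The means were 6.74 ± 1.14 and 3.64 ± 0.202 CPM (SD, n = 3 each), with all 3 Zeb1 (+/-) values below all 3 wild-type values. The log2 fold change, Zeb1 (+/-) over wild-type as throughout, was −0.89 ± 0.16 (SE; 95% confidence interval −1.25 to −0.53). Its edgeR Benjamini-Hochberg adjusted p of 0.0522 missed the threshold of 0.05. Without wild-type replicate 1 the log2 fold change was −1.03 and passed it, and over 15 other settings the adjusted p ran from 0.00094 to 0.274. With the structural-RNA split as a term the log2 fold change was −0.995.

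The comparison asked which mRNAs of resting peritoneal macrophages differ between wild-type and Zeb1 (+/-) mice. In Zeb1 (+/-) macrophages, genes that mark the small, monocyte-derived macrophages of the peritoneal cavity and genes of MHC class II antigen presentation were lower as sets, though not with a correlation estimated from these libraries, and 6 of 18 and 4 of 11 tested members fell. Markers of B cells were lower beside them as a set, likewise not with an estimated correlation, and 0 of 17 passed one by one. Ccr2, the chemokine receptor that draws monocytes into tissues, fell from 266 ± 11.2 to 173 ± 7.69 CPM (mean ± SD, n = 3 each). Mrc1, the mannose receptor, fell from 218 ± 20.6 to 111 ± 7.83 CPM. Cd74, the invariant chain that escorts MHC class II molecules, fell from 1907 ± 99.1 to 1331 ± 46.9 CPM. Mmp9, a secreted gelatinase, fell from 34.7 ± 1.84 to 19.0 ± 3.28 CPM. Cables1, a partner of cyclin-dependent kinases, rose from 7.70 ± 0.989 to 25.3 ± 0.764 CPM. The scavenger receptor Colec12 rose from 98.8 ± 2.91 to 185 ± 10.4 CPM. Cables1 and Colec12 both lie within 20 Mb of Zeb1 on chromosome 18. Of 12940 genes tested by the edgeR quasi-likelihood method, 76 changed, 20 of them higher and 56 lower in Zeb1 (+/-). Of these 14 passed 2-fold, 6 higher and 8 lower. All 76 had groups that did not overlap, as did 2578 of all tested genes (19.9%, where chance gives 10%).

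**Figure D1:**
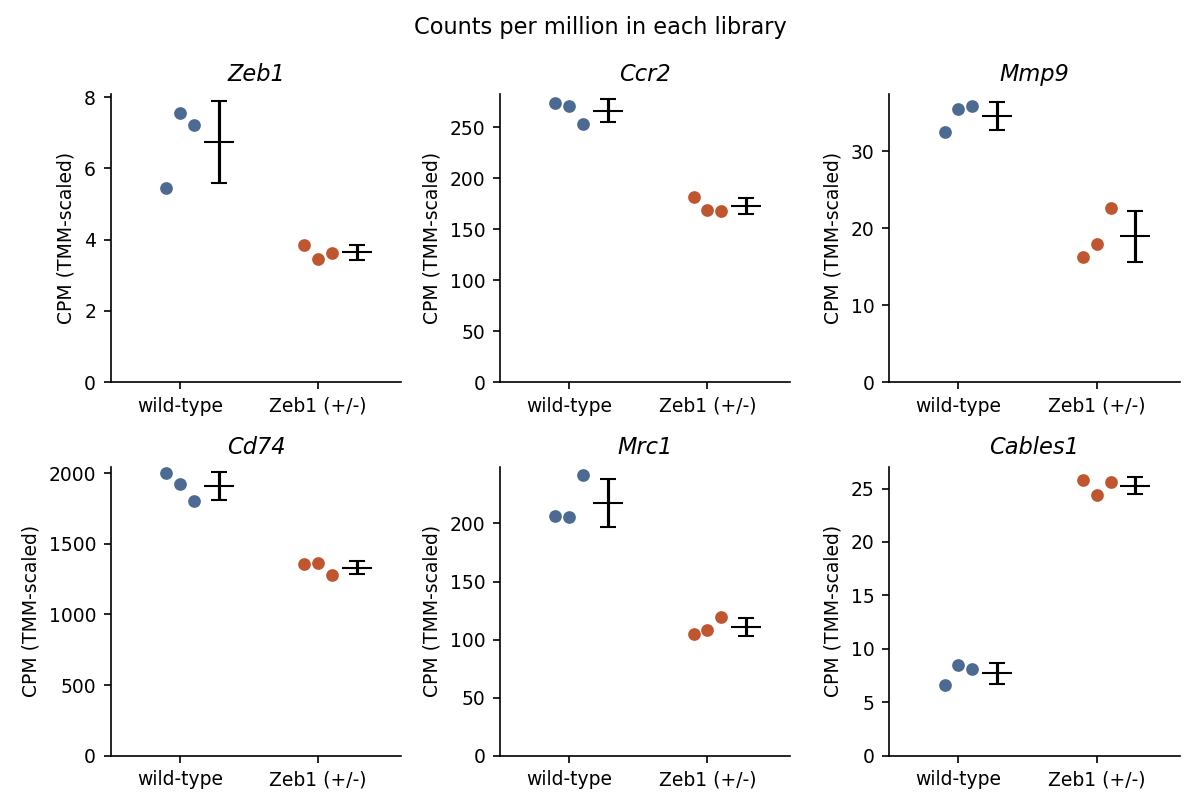
Expression in CPM (TMM-scaled, vertical axes from 0) of Zeb1, Ccr2, Mmp9, Cd74, Mrc1 and Cables1 in the 3 wild-type and 3 Zeb1 (+/-) libraries, one point per library, with the mean and SD as bars beside the points. All 3 Zeb1 (+/-) values lie below all 3 wild-type values for the first 5 genes and above them for Cables1, while Zeb1 itself missed the threshold with an adjusted p of 0.0522.

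The number of changed genes moved with single libraries. There were 4 higher and 1 lower without wild-type replicate 2, 13 and 15 without Zeb1 (+/-) replicate 1, 6 and 5 without Zeb1 (+/-) replicate 2, and 36 and 91 without Zeb1 (+/-) replicate 3. The 76 genes kept their direction, each at an unadjusted p under 0.05, in all 6 fits with 1 library left out. Because their groups did not overlap, the direction was all but fixed in these fits. With the structural-RNA split as a term 4 were higher and 27 lower, 7 of them among the 76. With the mean of B cell marker genes as a covariate 4 were higher and 0 lower, 2 of them among the 76 (Cables1 and Stard13). In that fit 1785 genes had an unadjusted p under 0.05. DESeq2 without the covariate called 220 genes lower.

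Small peritoneal macrophages are the minor, inflammation-linked population of the cavity. Of the 18 tested genes on the list fixed for them, 6 fell, none rose and 12 did not pass. Adjusted over the list alone, 11 were lower and 0 higher. Mrc1 fell by 0.97 ± 0.09 on the log2 scale (SE; adjusted p = 0.00347). The Fc receptor-like gene Fcrls fell by 0.65 ± 0.06 (adjusted p = 0.00683) and Ccr2 by 0.62 ± 0.07 (adjusted p = 0.00897). Retnla, a secreted product of alternatively activated macrophages, fell from 1136 to 744 CPM. The folate receptor gene Folr2 fell from 94.7 to 41.3 CPM and the phospholipase-like gene Plbd1 from 65.9 to 46.4 CPM. The scavenger receptor gene Cd163 was at 106 and 44.9 CPM (log2 fold change −1.23, adjusted p = 0.0988). Clec10a and Cd209a had log2 fold changes of 0.14 and 0.07. The list had a median log2 fold change of −0.49 and was lower as a set by camera (adjusted p = 3.06e-08). Its adjusted p was 0.314 with an estimated correlation and 0.0114 by fry. The monocyte list, which shares Ccr2 with it, had 11 tested members with 1 lower, 0 higher and 10 not past the threshold, and 3 lower adjusted over the list alone. Its median was −0.28 (camera adjusted p = 0.0067; adjusted p = 0.314 with an estimated correlation; fry 0.0105). With 1 library left out the medians ran from −0.57 to −0.36 for small peritoneal macrophages. For monocytes they ran from −0.47 (without Zeb1 (+/-) replicate 1) to −0.19 (without wild-type replicate 3). B cell markers were lower beside these lists (median −0.95, and −0.57 without wild-type replicate 3; adjusted p = 0.502 with an estimated correlation). With their mean as a covariate the medians were −0.64 for small peritoneal macrophages and −0.09 for monocytes, and the second was no longer past the threshold. With the structural-RNA split as a term these medians were −0.35 and −0.35, both past it. Among the 6 genes, Mrc1 alone passed in all 6 fits with 1 library left out. There were 5 calls lost without wild-type replicate 2, 4 without Zeb1 (+/-) replicate 2, 2 without Zeb1 (+/-) replicate 1, and 1 (Plbd1) without each of the other 3. In these fits the log2 fold changes stayed within 17.3% of the main ones. With the structural-RNA split as a term 4 calls were lost and with the B cell mean as a covariate all 6, and the adjusted p ran from 5.68e-21 to 0.292 over all other settings.

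MHC class II molecules present peptides to CD4 T cells. Of 11 tested genes on this list, 4 fell, 0 rose and 7 did not pass. Adjusted over the list alone, 8 were lower and 0 higher. H2-Eb1 fell by 0.54 ± 0.07 on the log2 scale (SE; adjusted p = 0.0185), from 609 to 418 CPM. Cd74 fell by 0.52 ± 0.07 (adjusted p = 0.0186), and H2-Aa and H2-Ab1 fell by 0.48 and 0.47 (adjusted p = 0.0246 each), from 807 to 577 and from 614 to 443 CPM. Ciita, the master transactivator of these genes, was at 32.7 and 21.2 CPM with a log2 fold change of −0.64 and an adjusted p of 0.0503. The list had a median of −0.43 and was lower as a set by camera (adjusted p = 3.06e-07). Its adjusted p was 0.272 with an estimated correlation and 0.00293 by fry. B cells also express these genes. The 16 B cell marker genes summed to 228 ± 92.5 CPM in wild-type and 119 ± 17.1 CPM in Zeb1 (+/-), a difference of −109. Without wild-type replicate 3, which had 334 CPM, that difference was −56.4. The 4 MHC class II genes that passed summed to 3936 ± 207 and 2769 ± 85.7 CPM, a difference of −1167 (−1266 without that library). These sums do not show how much of that difference B cells could account for. The level of MHC class II genes relative to the markers in B cells was not measured here. The median of the list was −0.51 with the B cell mean as a covariate and −0.42 with the structural-RNA split as a term. The list stayed past the threshold by camera in both fits. All 4 calls were lost without wild-type replicate 2 and without Zeb1 (+/-) replicate 2, 3 without Zeb1 (+/-) replicate 1, and 2 (H2-Aa and H2-Ab1) without wild-type replicate 1 and without Zeb1 (+/-) replicate 3. Their log2 fold changes in these fits lay within 11.8% of the main ones, and the adjusted p ran from 2.24e-10 to 0.216 over all other settings. All 4 were also lost with the structural-RNA split as a term and with the B cell mean as a covariate. Ciita passed without wild-type replicate 3 (−0.75), and was at −0.34 with the split and −0.98 with the covariate without passing.

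**Figure D2:**
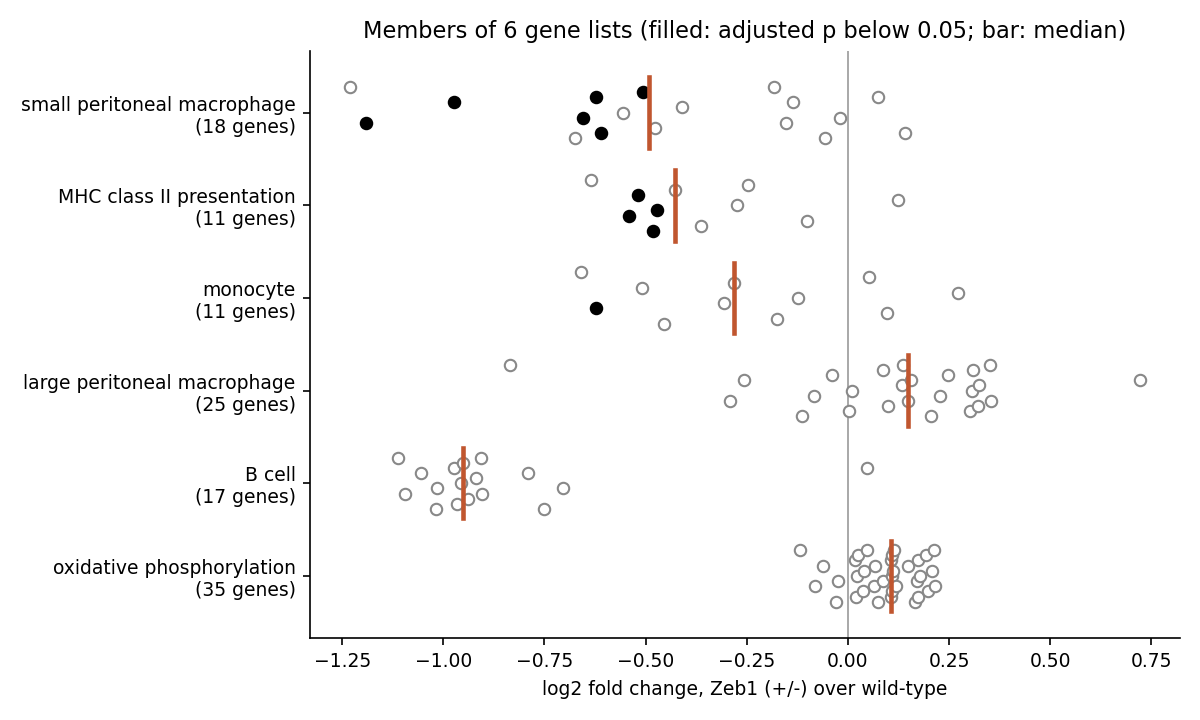
Log2 fold change, Zeb1 (+/-) over wild-type, of each tested member of 6 fixed gene lists (one circle per gene, horizontal axis; vertical scatter within a list has no meaning), with filled circles for genes past an adjusted p of 0.05 and a bar at the list's median. The medians are −0.49 for small peritoneal macrophages, −0.43 for MHC class II, −0.28 for monocytes, 0.15 for large peritoneal macrophages, −0.95 for B cells and 0.11 for oxidative phosphorylation.

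Large peritoneal macrophages are the resident majority of the cavity. None of the 25 tested genes on their list changed when adjusted over all genes, while adjusted over the list alone 7 were higher and 2 lower. The integrin gene Itga6 had a log2 fold change of 0.35 (adjusted p = 0.0689). The transcription factor gene Gata6, which sets the identity of these cells, had 0.31 (adjusted p = 0.115), and the scavenger receptor gene Marco −0.84 (adjusted p = 0.134). The list was higher as a set by camera (median 0.15, adjusted p = 0.0067), with adjusted p = 0.502 with an estimated correlation. That call was lost without wild-type replicate 3 (median 0.17) and with the B cell mean as a covariate (0.13), but not with the structural-RNA split as a term (0.20). Of the genes behind the sort, Adgre1, which encodes F4/80, was at 2186 and 2618 CPM (log2 fold change 0.26, adjusted p = 0.111). Itgam, which encodes CD11b, had a log2 fold change of 0.06 (adjusted p = 0.745), although 66.3% of its 50-base stretches also occur in the overlapping gene Gm49368. The list of core macrophage genes had 19 tested members with 0 changed, 1 higher adjusted over the list alone, and a median of −0.03 (adjusted p = 0.877; −0.10 to −0.00383 with 1 library left out).

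Among the other genes that rose, Cables1 rose by 1.72 ± 0.10 on the log2 scale (SE; adjusted p = 0.000446) and Colec12 by 0.91 ± 0.07 (adjusted p = 0.0014). Both lie near Zeb1, so DNA carried along beside the targeted allele remains a possible explanation for them, as described below. Stard13, which encodes a protein with a START domain, rose by 1.00 ± 0.09 (adjusted p = 0.00347). Cd200r3, a receptor gene of the CD200 receptor family, rose by 2.70 ± 0.27 (adjusted p = 0.00708) from a low level, 0.467 to 3.06 CPM. These 4 passed in all 6 fits with 1 library left out. With the structural-RNA split as a term their log2 fold changes were 1.64, 0.91, 0.90 and 3.05. Cd200r3 did not pass in that fit. Lpl, the lipoprotein lipase, rose from 700.4 to 1232 CPM (0.81 on the log2 scale). Gfpt2, an enzyme of the hexosamine pathway, rose from 2.51 to 7.13 CPM, and Tdo2, a tryptophan dioxygenase, from 1.03 to 3.45 CPM. Spp1, the secreted phosphoprotein osteopontin, rose from 0.999 ± 0.178 to 6.16 ± 3.74 CPM (adjusted p = 0.0482). Of its 50-base stretches 11.6% also occur in the overlapping gene Gm42793. Tspan7, Pi16, Cped1, Vmn2r26 and C1ra rose by 1.70, 0.74, 0.63, 0.57 and 0.55. In other genes occur 17.1% of the stretches of Vmn2r26 and 50.8% of those of C1ra, mostly shared with C1rb. Of the 9 genes from Lpl to C1ra, 9 calls were lost without wild-type replicate 2, 8 without Zeb1 (+/-) replicate 2 and 7 without wild-type replicate 3. There were 6 lost without wild-type replicate 1, 5 without Zeb1 (+/-) replicate 1 and 2 without Zeb1 (+/-) replicate 3. In these fits the log2 fold changes stayed within 23.3% of the main ones. All 9 calls were lost with the structural-RNA split as a term and with the B cell mean as a covariate, where Tspan7 and C1ra were at 0.98 and 0.29, and the adjusted p ran from 3.7e-09 to 0.398 over all other settings.

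Among the other genes that fell, the carbonyl reductase gene Cbr2 fell by 1.23 ± 0.16 on the log2 scale (SE; adjusted p = 0.0186), from 115 to 49.1 CPM. Of its 50-base stretches 12.1% also occur in Gm11771. Tenm4, which encodes a teneurin, fell by 1.17 and the transcription elongation factor gene Aff3 by 1.12. The reticulocalbin gene Rcn3 fell by 1.13 and Tmem8, a membrane protein gene, by 0.96. The pseudogene Nlrp1c-ps fell by 1.23 and Hpgd, which breaks down prostaglandins, by 1.13. The Ras-like gene Diras2 fell by 0.87 and the apolipoprotein gene Apoc4 by 0.96. Cxcr5, a chemokine receptor of B cells, fell by 0.88. Its locus (chromosome 9, 44511787 to 44561877) overlaps Bcl9l on the opposite strand (44482825 to 44511896), which fell by 0.62. The overlap is confined to the edge of each locus. Whether counting was strand-specific is not stated. Of these 10 genes, 10 calls were lost without wild-type replicate 2, 9 without Zeb1 (+/-) replicate 1, and 9 without Zeb1 (+/-) replicate 2. There were 6 lost without wild-type replicate 1, 4 without wild-type replicate 3 and 3 without Zeb1 (+/-) replicate 3. In these fits the log2 fold changes stayed within 19.0% of the main ones. Cbr2 alone passed with the structural-RNA split as a term and 0 with the B cell mean as a covariate, and the adjusted p ran from 4.15e-13 to 0.294 over all other settings.

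Lists for macrophage functions held fewer changed genes. Of 17 alternative-activation genes 2 fell (Mrc1 and Retnla) and 0 rose. Adjusted over the list alone 6 were lower and 1 higher (Arg1, log2 fold change 0.89), and the set did not pass (median −0.19, adjusted p = 0.0573). Of 25 phagocytosis and scavenger receptor genes 2 fell, Mrc1 and the receptor tyrosine kinase Axl, which binds apoptotic cells through Gas6. Adjusted over the list alone 6 were lower and 2 higher. Axl fell from 117 to 70.4 CPM, a change of −0.73 on the log2 scale. The set was lower (median −0.05, camera adjusted p = 0.0200; adjusted p = 0.502 with an estimated correlation). Of 25 chemokine and cytokine receptors 1 fell, Ccr2, with 3 lower and 1 higher adjusted over the list alone and a median of −0.12 (adjusted p = 0.0656). Of 16 chemokines 0 changed, with 1 lower adjusted over the list alone, Ccl6 (−0.31, and −0.17 with the B cell mean as a covariate). The set was lower (median −0.26, camera adjusted p = 0.0213; adjusted p = 0.502 with an estimated correlation). Of 23 matrix and protease genes Mmp9 fell and Spp1 rose, with 2 lower and 2 higher adjusted over the list alone. The median was −0.01 and the mean 0.15 (adjusted p = 0.719). Of 20 complement and coagulation genes C1ra rose, with 1 higher and 1 lower (F13a1, −0.66) adjusted over the list alone, and a median of −0.02 (adjusted p = 0.877; camera read the set as higher). Of 29 cholesterol and lipid genes Lpl rose, with 3 higher and 4 lower adjusted over the list alone, among them Apoe (−0.45), and a median of −0.03 (adjusted p = 0.548). The set calls for chemokines were lost without wild-type replicate 1, wild-type replicate 3 or Zeb1 (+/-) replicate 1 (medians −0.16, −0.26 and −0.07). Those for phagocytosis were lost without wild-type replicate 3 or Zeb1 (+/-) replicate 1 (−0.11 and −0.06). Both were lost with the B cell mean as a covariate (−0.23 and −0.16). Mmp9 was not past the threshold without wild-type replicate 2 or Zeb1 (+/-) replicate 2 (−0.84 and −0.81), and was at −0.91 with the structural-RNA split as a term. Axl was not past it without wild-type replicate 1 or 2 or Zeb1 (+/-) replicate 1 or 2 (−0.70, −0.67, −0.72 and −0.64). Mmp9, Axl, Tnfaip2 and Cd2, the last from the T and NK cell list, did not pass with the structural-RNA split as a term or with the B cell mean as a covariate. The alternative-activation set passed without wild-type replicate 2 or Zeb1 (+/-) replicate 3 (medians −0.20 and −0.19), and the receptor set without Zeb1 (+/-) replicate 3 (−0.12). Over the 6 fits with 1 library left out the medians ran from −0.31 to −0.17 for alternative activation, −0.15 to −0.06 for phagocytosis, −0.18 to −0.04 for receptors and −0.35 to −0.07 for chemokines.

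Genes of inflammatory signalling moved little one by one. Of 18 genes of classical inflammatory activation Tnfaip2 fell (−0.47, adjusted p = 0.0482), 2 were lower adjusted over the list alone, and the set did not pass (median −0.06, adjusted p = 0.132). The call on Tnfaip2 held without wild-type replicate 3 alone and its log2 fold change was −0.39 without wild-type replicate 2. The set passed without Zeb1 (+/-) replicate 2 (−0.09), and its median ran from −0.12 to −0.00244 with 1 library left out. None of 32 type I interferon response genes changed, 4 were lower adjusted over the list alone (Ifi27l2a, −0.49, among them), and 28 of the 32 had negative log2 fold changes. That set was lower (median −0.16, camera adjusted p = 0.00154; adjusted p = 0.698 with an estimated correlation), except without Zeb1 (+/-) replicate 1 (−0.10) and with the structural-RNA split as a term (−0.12). Its median ran from −0.30 (without Zeb1 (+/-) replicate 3) to −0.08 (without wild-type replicate 2) and was −0.37 with the B cell mean as a covariate. Of 24 interferon gamma response genes 0 changed, with 1 lower and 1 higher adjusted over the list alone, and the set did not pass (median −0.09, adjusted p = 0.109), although it did without wild-type replicate 1 or Zeb1 (+/-) replicate 2 (−0.14 in each) and had medians of −0.14 to −0.04 with 1 library left out. Of 23 immediate-early genes, which respond to cell handling within minutes, 0 changed, with Junb (−0.47, adjusted p = 0.0988) lower adjusted over the list alone. That set was lower (median −0.18, camera adjusted p = 0.00154; adjusted p = 0.698 with an estimated correlation), except without wild-type replicate 1 (−0.12), without Zeb1 (+/-) replicate 1 (−0.15) and with the structural-RNA split as a term (−0.07). Its median ran from −0.34 (without Zeb1 (+/-) replicate 3) to −0.12 (without Zeb1 (+/-) replicate 2) and was −0.46 with the B cell mean as a covariate. Without Zeb1 (+/-) replicate 3 the log2 fold changes of Junb and Ifi27l2a, −0.57 and −0.62, passed. They were −0.26 and −0.32 with the structural-RNA split as a term and −0.81 and −0.82 with the B cell mean as a covariate, without passing.

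None of the genes on the lists for energy metabolism, protein folding, lysosomes and the cell cycle changed. Of 35 oxidative phosphorylation genes 30 had positive log2 fold changes, with a median of 0.11, and the set was higher (camera adjusted p = 0.00148; adjusted p = 0.698 with an estimated correlation). Ndufb9, a subunit of complex I, had the smallest p, with a log2 fold change of 0.21 (adjusted p = 0.184; 15.6% of its 50-base stretches also occur in the overlapping gene Gm49356). The 25 glycolysis and hypoxia genes, Ldha (0.24) among them, had a median of 0.08. The set was higher (camera adjusted p = 0.0233; adjusted p = 0.502 with an estimated correlation). The 24 genes of the unfolded protein response, led by the chaperone gene Calr (0.31), had a median of 0.19. The set was higher (camera adjusted p = 0.0164; adjusted p = 0.762 with an estimated correlation). Of these set calls, that for glycolysis was lost without wild-type replicate 2 or 3 or Zeb1 (+/-) replicate 1 or 3 (medians 0.05, 0.09, 0.11 and 0.11). That for the unfolded protein response was lost without wild-type replicate 2 or 3 or Zeb1 (+/-) replicate 3 (0.11, 0.10 and 0.07). With 1 library left out the medians ran from 0.07 (without wild-type replicate 2) to 0.15 for oxidative phosphorylation, 0.05 to 0.17 for glycolysis and 0.07 to 0.29 for the unfolded protein response. All 3 set calls were lost with the B cell mean as a covariate (0.05, 0.07 and −0.09 for oxidative phosphorylation, glycolysis and the unfolded protein response), and passed with the structural-RNA split as a term (0.12, 0.16 and 0.31). The 35 cell cycle genes had a median of 0.13 (Mcm6 0.29, with 0.17 under the split and 0.49 under the covariate; adjusted p = 0.214). The 29 lysosome and autophagy genes had a median of 0.01 (Mcoln1 −0.28; adjusted p = 0.902), and the 17 heat shock genes 0.10 with a mean of −0.03 (adjusted p = 0.299). Hspd1 led the last of these at 0.34, with 39.7% of its 50-base stretches also in other genes, mostly a pseudogene. The 13 protein genes of the mitochondrial genome had a median of 0.09 (adjusted p = 0.0983; 0.00915 to 0.17 with 1 library left out), with mt-Nd3 (1.09, adjusted p = 0.0575) higher adjusted over the list alone. Of the stretches of mt-Nd3 98.0% are shared with the nuclear pseudogene Gm28438. Without wild-type replicate 1 mt-Nd3 (1.43), its list (0.14) and the heat shock list (0.31) passed. The heat shock list also passed with the structural-RNA split as a term (0.37). The cell cycle list passed without wild-type replicate 3 (0.32) or Zeb1 (+/-) replicate 3 (0.22) and with the B cell mean as a covariate (0.62). It passed as a lower set with the structural-RNA split as a term (−0.33).

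Few genes tied to ZEB1 in epithelial cells had enough counts to be tested. Of the epithelial and junction genes reported to be repressed by ZEB1, 5 were tested, 0 changed, and 2 were higher and 1 lower adjusted over the list alone. St14, a membrane serine protease gene, had a log2 fold change of 0.62 (adjusted p = 0.0539), and the tight-junction gene Ocln 0.26. The median was −0.29, the mean −0.02, and camera read the set as higher without passing (adjusted p = 0.877). With 1 library left out the median ran from −0.28 to −0.10 (without wild-type replicate 1), and it was −0.08 with the structural-RNA split as a term and −0.04 with the B cell mean as a covariate. Of the mesenchymal genes 10 were tested and 0 changed (median −0.11, mean 0.01, adjusted p = 0.719), with Tgfb2 at 0.25 (0.38 with the split and 0.0255 with the covariate). St14 passed without wild-type replicate 1 (0.72).

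Markers of other cell types were read as a check of the sort. Of 17 B cell genes 0 changed when adjusted over all genes and 15 were lower adjusted over the list alone. The list had a median of −0.95 and a camera adjusted p of 1.21e-08 (adjusted p = 0.502 with an estimated correlation). Ighm, the heavy chain of IgM, was at 80.7, 71.6 and 142.5 CPM in wild-type replicates 1, 2 and 3 and at 61.1, 50.2 and 44.4 CPM in Zeb1 (+/-) replicates 1, 2 and 3. Cd79a, a part of the B cell receptor, averaged 16.9 and 8.31 CPM, and the kinase gene Blk had a log2 fold change of −1.09 (adjusted p = 0.0895). Blk was at −0.34 with the B cell mean as a covariate. The B cell median ran from −1.10 to −0.57 (without wild-type replicate 3) with 1 library left out and was −1.48 with the structural-RNA split as a term. Of 10 T and NK cell genes Cd2 fell, from 16.3 to 10.5 CPM, with 1 lower adjusted over the list alone. Cd2 was not past the threshold without wild-type replicate 1 or 2 or Zeb1 (+/-) replicate 1 or 2 (−0.57, −0.65, −0.64 and −0.67). The set was lower (median −0.46, camera adjusted p = 0.00568; adjusted p = 0.509 with an estimated correlation). That set call was lost without wild-type replicate 1 (−0.22) and with the B cell mean as a covariate (−0.17), and the median was −0.65 without wild-type replicate 2. Of 12 dendritic cell genes 0 changed, with Batf3 (−0.61) lower adjusted over the list alone. The set was lower (median −0.32, camera adjusted p = 0.0200; adjusted p = 0.566 with an estimated correlation). It did not pass without wild-type replicate 1 (−0.20), without Zeb1 (+/-) replicate 2 (−0.22), or with the structural-RNA split as a term (−0.21) or the B cell mean as a covariate (−0.26). Of 8 neutrophil genes Mmp9 fell, 1 was lower and 1 higher (Hdc) adjusted over the list alone, and the median was 0.27 (adjusted p = 0.592). Of 8 eosinophil and mast cell genes 0 changed, 2 were higher adjusted over the list alone (Hdc, 0.72, and Ccr3, 1.22), and the median was 0.17 (adjusted p = 0.299). Hdc passed without Zeb1 (+/-) replicate 3 (0.79) and Batf3 without wild-type replicate 3 (−0.75). Hdc was at 0.40 with the B cell mean as a covariate and Batf3 at −0.25 with the structural-RNA split as a term, without passing. The 6 erythroid and platelet genes had a median of −1.62 (adjusted p = 0.613), and −0.19 without wild-type replicate 1. That median was −0.13 with the structural-RNA split as a term and −3.48 with the B cell mean as a covariate. Hba-a1, of whose 50-base stretches 72.3% also occur in Hba-a2, had a log2 fold change of −1.83 (adjusted p = 0.317) and −0.44 without wild-type replicate 1. Hba-a1 was at −0.26 with the split and −3.72 with the covariate. The 4 haemoglobin genes summed to 211 CPM in wild-type replicate 1 and to 2.86 to 46.7 CPM in the other 5 libraries. Xist was the only sex-linked gene tested (log2 fold change −0.09, adjusted p = 0.673), and 0 of the mesothelial and fibroblast genes had enough counts to be tested.

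Cables1 (ENSMUSG00000040957.14, 11839220 to 11945630) and Colec12 (ENSMUSG00000036103.8, 9707595 to 9882644) lie on chromosome 18 of GRCm38 within 20 Mb of Zeb1. Of the 64 other tested genes in that window 2 changed (3.13%), against 74 of 12846 elsewhere (0.576%). The odds ratio was 5.57 (95% confidence interval 0.648 to 21.7, two-sided Fisher's exact p = 0.0546). At an unadjusted p under 0.05 there were 20 of the 64 (31.3%), 14 higher and 6 lower, against 14.5% elsewhere (odds ratio 2.68, two-sided Fisher's exact p = 0.000568). Gata6 was among them.

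**Figure D3:**
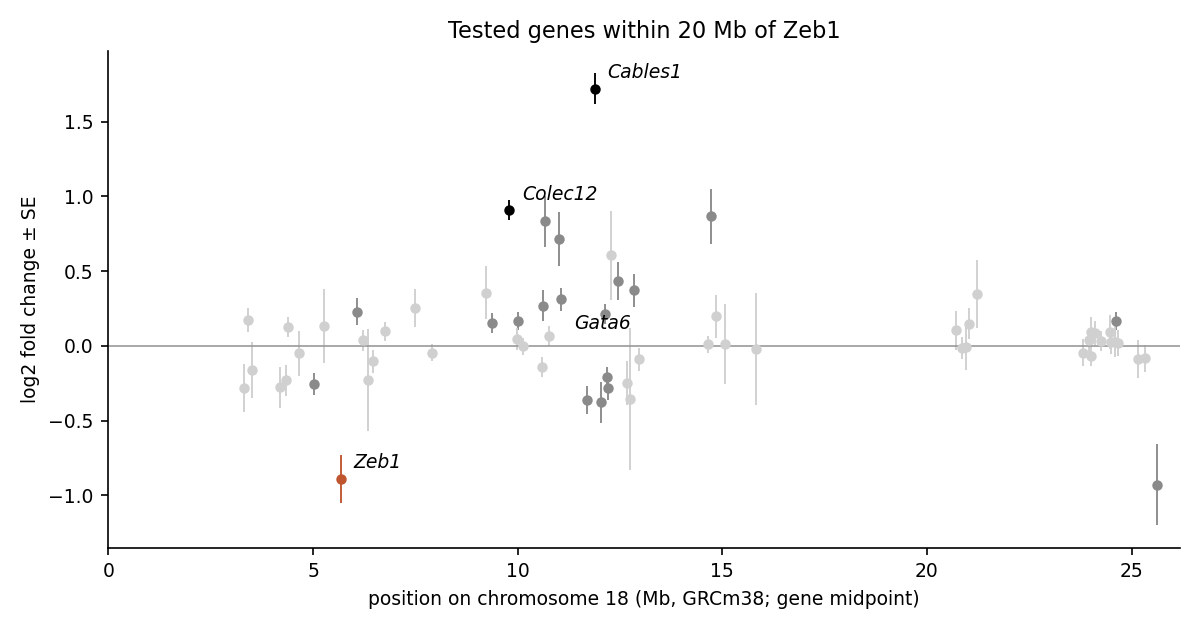
Log2 fold change, Zeb1 (+/-) over wild-type, with its SE as a bar (vertical axis), of each tested gene against its midpoint on chromosome 18 in Mb of GRCm38 (horizontal axis), for the genes within 20 Mb of Zeb1. Zeb1 is drawn in orange, the 2 changed genes (Cables1 and Colec12) in black, genes at an unadjusted p under 0.05 in dark grey and the rest in light grey; 14 of the 20 genes in black or dark grey are higher in Zeb1 (+/-).

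The p-values measure the spread between libraries, each a pool of 2 mice, in 3 libraries per genotype, where the biological coefficient of variation was 9.93%. Across the 31 tested lists 14 passed by camera with a preset correlation (4 higher, 10 lower), 0 with a correlation estimated from these libraries and 3 by fry, which were small peritoneal macrophage, MHC class II and monocyte. By camera 9 passed without Zeb1 (+/-) replicate 1.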

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

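The structural-RNA split and the B cell covariate were chosen after the data were seen. The other alternatives were fixed in advance. All 37 named genes past the threshold kept their direction in all 15 alternatives run for single genes, as did the 22 others. For the 37, whose groups did not overlap, this was all but fixed in the fits with 1 library left out. Calls were less stable. Only 5 of the 37 (Cables1, Colec12, Stard13, Mrc1 and Cd200r3) passed with each library left out. Of the 37, 32 were lost without wild-type replicate 2 and 29 without Zeb1 (+/-) replicate 2, against 9 without Zeb1 (+/-) replicate 3. These fits have equal numbers of libraries, so fewer samples alone do not account for the difference, whose cause was not tested. Against 20 genes higher and 56 lower, RLE factors gave 20 and 54, the stricter filter 19 and 55, limma-voom 20 and 59, and robust moderation 21 and 68. No low-count filter, with 21101 genes tested, gave 207 and 315, and the Wald test of DESeq2 109 and 220. An adjusted p under 0.1 gave 61 and 153, and a change of at least 2-fold, which is stricter by construction, 6 and 8. The unfiltered fit shared 76 of the 76 genes and DESeq2 75. With 1 library left out the counts ran from 4 to 36 higher and from 1 to 91 lower. The structural-RNA split as a term gave 4 and 27, and the B cell covariate 4 and 0. Both use up a degree of freedom and are partly confounded with genotype. The low structural-RNA class held wild-type libraries only, and the B cell mean was higher in every wild-type library than in any Zeb1 (+/-) library. Such confounding itself widens the SE of a log2 fold change. Its median over tested genes was 0.144 and 0.159 in these fits, against 0.101. The replicate number as a block gave 6 and 9, with 11 of the 76 shared and 4 others (Cd163, Cd209f, Gas6 and Arg1, named after their values were seen). Deviations from the genotype means correlated at −0.25, −0.03 and −0.17 between samples of equal number, and no sample correlated best with its own number. The numbers thus gave no pairing of the samples. The block too uses up degrees of freedom. In the groups of called genes whose lost calls are counted together above, it moved the log2 fold changes by at most 6.38%. Whether the lost degrees of freedom alone account for the fewer calls was not tested. Zeb1 (−0.89) passed the threshold without a filter (−0.87), by DESeq2 (−0.88), with robust moderation (−0.89) and, among fits with 1 library left out (−1.03 to −0.79), without wild-type replicate 1. Its adjusted p ran from 0.00094 to 0.274, and the cause was not tested. Of 31 lists 14 passed by camera. With 1 library left out 9 to 15 did, 5 with the B cell covariate, 13 with the split, 3 by fry, and 0 with an estimated correlation, which allows for members that vary together. Some medians changed sign. With the structural-RNA split these were matrix and proteases (0.0953), complement (0.0439), cell cycle (−0.33), mesenchymal (0.14), mitochondrial (−0.0299) and eosinophil and mast cell genes (−0.18). With the B cell covariate they were lysosome (−0.00337), unfolded protein response (−0.0921), heat shock (−0.41) and neutrophil genes (−0.0951). The cell cycle set passed as lower with the split and as higher with the covariate (0.62). Within wild-type both terms set replicate 3 apart from replicates 1 and 2, so they are not independent checks. Structural RNA was at 42.2 CPM against 4.14 and 8.69, and the B cell mean at 3.43 log2 CPM against 2.56 and 2.46. The block changed the sign for matrix and proteases (0.00171) and the absence of a filter for complement (0.00165). With 1 library left out the medians ran from −0.0387 to 0.0462 for matrix and proteases, −0.0480 to 0.0240 for complement, −0.0826 to 0.0328 for cholesterol and lipids, and −0.00898 to 0.0219 for lysosome genes. They ran from −0.12 to 0.32 for cell cycle, −0.17 to 0.0494 for mesenchymal, −0.17 to 0.31 for heat shock, −0.0365 to 0.37 for neutrophil, and −0.0730 to 0.41 for eosinophil and mast cell genes. The cause was not tested. The B cell list is not tested against its own mean, which as a covariate sets its median near 0 (0.0205), and the T and NK cell and the eosinophil and mast cell lists have none under the stricter filter. At these totals and this number of libraries, simulated 1.5-fold changes were found in 66.9% of cases and 2-fold changes in 86.7%. Those counts followed the dispersion trend alone, so the rates hold for the simulated counts and may differ in the libraries themselves.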

Other observations

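The gene families in this paragraph were chosen after their values were seen, as was each test below except the count of other splits and the odds ratio near Zeb1. Of 17 tested semaphorins and plexins, guidance ligands and receptors that also act between immune cells, 14 had negative log2 fold changes (14 with RLE factors as well; median −0.28, and −0.39 to −0.14 with 1 library left out). Plxnd1 fell from 137 ± 7.17 to 82.1 ± 7.38 CPM (−0.74, adjusted p = 0.0101) and Sema4a from 70.1 ± 5.97 to 43.4 ± 1.95 CPM (−0.69, adjusted p = 0.0123), with 15 not past the threshold. Of 19 integrin genes Itgb1, the beta 1 chain, rose by 0.41 (adjusted p = 0.0328) and Itgal, the alpha chain of LFA-1, fell by 0.79 (adjusted p = 0.0482). Slfn4, a Schlafen gene of myeloid cells, fell from 684 to 440 CPM (−0.64), the lectin gene Clec4a1 from 72.2 to 49.2 CPM (−0.55), the inflammasome gene Nlrp1b from 14.4 to 8.57 CPM (−0.76) and the neonatal Fc receptor gene Fcgrt from 320 to 228 CPM (−0.49). Of these 8 genes 8 passed without Zeb1 (+/-) replicate 3, 6 without wild-type replicate 3, 4 without wild-type replicate 1, 3 without Zeb1 (+/-) replicate 1, 2 without Zeb1 (+/-) replicate 2 and 0 without wild-type replicate 2, where their log2 fold changes lay within 16.2% of the main ones. None of the 8 passed with the structural-RNA split as a term or with the B cell mean as a covariate. Apolipoprotein genes were mostly below 0, with Apoe at −0.45 (adjusted p = 0.0505) and Apoc2 at −0.36 (adjusted p = 0.0821), and Apoc4 alone past the threshold. Of 78 ribosomal protein genes 77 had positive log2 fold changes, with TMM and with RLE factors, and a median of 0.16. Of these genes 0 passed by edgeR and 34 had an unadjusted p under 0.05, against 1884 of all 12940 tested genes. Such genes can vary together between libraries, so these are not independent results. Their share of counts was 3.94%, 3.67% and 3.91% in wild-type replicates 1, 2 and 3. It was 4.07%, 4.44% and 4.13% in Zeb1 (+/-) replicates 1, 2 and 3. With the B cell mean as a covariate 7 were negative.

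With 6 libraries there are 10 ways to part them 3 and 3, too few for a share under 0.05. The real split gave 76 genes and the highest other split 0, so 1 of 10 gave as many, and it gave 14 lists by camera against 13 for the highest other split, again 1 of 10.

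At an unadjusted p under 0.05, the share of genes near Zeb1 on chromosome 18 (31.3%) was higher than elsewhere (14.5%). A candidate explanation is DNA from the strain in which the targeted allele was made, carried along beside it, but the odds ratio of 5.57 rested on 2 genes with an interval that includes 1, so this remains open, as does an effect of Zeb1 on its neighbours, which was not tested. A general tendency to cluster was argued against for genes at an unadjusted p under 0.05: of 136 other windows of 20 Mb, 0% held as high a share of such genes as the 31.3% around Zeb1, and the highest held 26.1%. Counted by adjusted p, 17 of the 136 windows held 2 or more changed genes and 2 held as high a share of them. For Cables1 and Colec12 themselves such clustering was therefore not excluded. These counts do not weigh the size of p. Cables1 and Colec12 had the 2 smallest of all tested genes (edgeR, unadjusted p = 3.45e-08 and 2.17e-07). Gata6 lies in the window around Zeb1, so its value of 0.31 shares this open reading.

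The 29 tested members of the small peritoneal macrophage and MHC class II lists were lower together, with a median of −0.47. With the B cell mean as a covariate the median was −0.54, with 23 of the 29 negative. It ran from −0.60 to −0.48 with 1 library left out. This does not settle whether B cells passing the sort in different numbers were the whole cause. The B cell mean did not overlap between genotypes (2.46 to 3.43 log2 CPM in wild-type, 1.75 to 2.12 in Zeb1 (+/-)). Its effect and that of genotype therefore cannot be fully told apart. The 10 called members lost their calls with that covariate, at a median log2 fold change of −0.60 against −0.58 in the fit without it, while their median SE was 0.116 against 0.0701. The change was larger in 7 of them and smaller in 3 (Mrc1, Retnla and Folr2, the last at −0.84 against −1.19), while the SE was wider in all 10. The structural-RNA split left a median of −0.42 and 2 of the 10 calls, but that value sets wild-type replicate 3 alone against the Zeb1 (+/-) libraries, so the split and genotype cannot be told apart for the other wild-type libraries. A lower share of small peritoneal macrophages among the sorted cells may also account for it: such a share lowers the genes of these cells alike, whereas the log2 fold changes of the 18 small peritoneal macrophage members had an SD of 0.407, but the tables do not say which genes only these cells express, so this stays open beside a lower level per cell. The genotype itself, which the design names, was not separated from these by any test here.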
